A study of Homo sapiens with 5 samples.

How the data were processed

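RNA polymerase II (RNAPII) was mapped by ChIP-seq against its largest subunit, RPB1, in RPE1 cells, an hTERT-immortalised human retinal pigment epithelial line that carried, per the labels, an inducible Cas9 and knockouts of p53 and of the puromycin resistance gene. The 5 samples fell into 3 groups by their titles: WT (3 samples), CFAP20-KO (1 sample) and CFAP20/CCNC-dKO (1 sample). Per the labels' protocols, cells were crosslinked with disuccinimidyl glutarate and formaldehyde, and Drosophila chromatin was added to each immunoprecipitation as a spike-in: 40 ng to 28 µg of chromatin for WT and CFAP20-KO, and 32.6 ng to 22 µg for CFAP20/CCNC-dKO. The labels name an RPB1 antibody of 1 supplier for WT and of another supplier for both knockouts. The catalogue number given for the WT antibody is also the one given for the spike-in antibody, so this label may be wrong, and antibody and genotype cannot be told apart in any comparison with WT.

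The authors deposited RNAPII density as a coverage signal in bins, and no counts were used here. Per the submitters' processing notes, the tools were FastQC 0.11.9, Trim Galore 0.6.5, BWA 0.7.17, SAMtools 1.11, HOMER 4.8.2, STAR 2.7.7a and R 4.0.5, with the builds GRCh38/hg38 and BDGP6; which tool made which file was not given in the sources used here. For replicate 1 of each genotype, the deposited signal covered 5 kb on either side of transcription start sites (TSSs) in 10-bp bins and was spike-in normalized, per the file names. For the 3 WT replicates, the deposited signal covered 100 kb on either side of replication origin centres in 200-bp bins. The origins were mapped by OK-seq (sequencing of Okazaki fragments). The normalization of this signal was not given in the sources used here, so mainly ratios within a library were taken from it. Promoter ratios between WT libraries were centred on their median. Densities of single origins were averaged over libraries whose scales may differ. A deposited table listed the TSSs with gene lengths and a WT BrU-seq gene body value, a measure of nascent transcription whose scale was not given, and another listed 2040 origins with the nearest gene, selected, per the file name, for an empty 5 kb upstream of a TSS by a procedure not given in the sources used here. These are the authors' values with no error. 2 further columns of per-sample values were not used. Values near overlapping windows showed that bins ran in the direction of transcription of the gene (TSSs) or of the nearest gene (origins).

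Every deposited TSS value was a whole multiple of 1 step within 0.02 steps, 0.0444 in WT, 0.181 in CFAP20-KO and 0.110 in CFAP20/CCNC-dKO, and isolated fragments covered 145, 298 and 319 bp. Dividing coverage by step and length gave equivalent fragments, 6766716, 846896 and 1185156 over all TSS windows. A TSS above the median promoter density held a median of 116 equivalent fragments in WT, 14.4 in CFAP20-KO and 16.5 in CFAP20/CCNC-dKO, so values for single genes in the knockouts are imprecise. 95% intervals of single-gene ratios are Clopper-Pearson intervals from these fragments. Where a library had less than 0.5 equivalent fragments, no ratio is given, only the limit of this interval that is nearer to no change. Intervals and limits cover counting error only.

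Of 9944 listed TSSs, 9787 (9767 genes) had values in all 3 libraries and were analysed. The listed positions were compared with GENCODE 44 on the same build: 9429 lay within 1 kb of a transcript start of the same gene, and 187 had a gene identifier absent from that release. Promoter density was the mean from -200 to 500 bp, gene body density the mean from 2000 to 5000 bp, and flank density the mean from 2000 to 4500 bp on both sides. Gene body medians over TSSs and correlations with BrU-seq used genes of at least 5000 bp. Gene body values of gene lists, of single genes, of TSSs near origins and of BrU-seq classes also include shorter genes. There the window can run past the gene end. Log2 ratios used a pseudocount of 0.0424, 10% of the median promoter density, and so understate changes of low genes. Medians were taken over the 4894 TSSs above the median of the mean promoter density of the 3 libraries, 4397 of them in genes of at least 5000 bp, with bootstrap 95% intervals (1000 draws) that cover the choice of TSSs only. With 1 library per genotype no test between genotypes was possible and no p-value is given. Promoters at least 1.5-fold higher or lower were counted with 1 TSS per gene (4892 genes) relative to the median ratio. For 23 gene lists, the median log2 ratio of the measured members was placed among 10000 random lists matched on mean promoter density in 20 bins; lists with fewer than 3 measured members were not placed. Counts of list members past 1.5-fold use the same centre. In WT, origin centres (within 5 kb) were compared with flanks (75 to 100 kb), and the positive side (5 to 50 kb) with the negative side, by the log2 ratio of mean density per library with an exact two-sided sign-flip permutation test, whose smallest possible p with 3 libraries is 0.25. Nothing in the labels says that the WT replicates came from separate cultures, so this p measures only the spread between these samples, which may be technical.

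As a reference for the spread between libraries of 1 genotype, promoters inside the origin windows were read in the 3 WT libraries (1791 TSSs, of which 1211 were above the median promoter density), each library divided by its median flank density. These flanks overlap the gene body window, and the genotype ratios are not relative to flanks, so the SD between WT libraries is a rough reference. Shares of promoters past 1.5-fold between WT libraries used 200-bp bins and a pseudocount of 10% of each library's median promoter density at these TSSs. The genotype shares used 10-bp bins and a pseudocount of 0.0424. Wider bins and a relatively larger pseudocount lower such shares, so the WT shares may be too low. The WT reference, the segments of differing flank density and the GC content of TSS windows were added after the data were examined. Segments were runs of at least 30 neighbouring autosomal TSSs whose running median flank log2 ratio (31 TSSs) passed 0.35 in the same direction in both knockout libraries against WT.

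The genes named followed a rule fixed before the data were examined, as were the windows, filters, lists and most alternatives. CFAP20 and CCNC were always to be named. In each comparison the 8 genes with the highest and the 8 with the lowest promoter ratio among those above the median promoter density were named, with up to 4 members of each list by mean promoter density, and the 5 origins with the highest density within 5 kb. Some genes that this rule takes are left out of the text and of the alternatives for single genes, but stay in all medians, counts and list results. Alternatives covered the windows, the pseudocount, the density filter, the scaling, the choice of TSS, the distance to origins, summaries over origins and leaving out each WT replicate.

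The 1.5-fold rule was tested on simulated fragments for the 4892 genes. In CFAP20-KO against WT, 86% of genes made 2-fold higher, 80% of genes made 2-fold lower and 100% of genes made 4-fold higher or lower were recovered, and 14.0% of unchanged genes also passed the rule. Of unchanged genes, 9.23% passed in CFAP20/CCNC-dKO against WT and 22.7% in CFAP20/CCNC-dKO against CFAP20-KO. The simulated fragments held counting error only and no other spread between libraries. For the measured libraries, the recovery may thus be too high and the shares of unchanged genes too low. These simulations set the first library of each comparison higher than the second, whereas measured promoter density was lower in CFAP20/CCNC-dKO. For this reason too, the last 2 shares may be too low. A simulation of counting error at the measured median ratios gave 653 and 1237 of 4892 genes past 1.5-fold in these 2 comparisons. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.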

Results

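RNAPII occupancy was compared between RPE1 cells with intact CFAP20 (WT), cells lacking CFAP20 (a protein named for its association with cilia and flagella), and cells lacking both CFAP20 and CCNC (cyclin C, a subunit of the kinase module of Mediator). The series addresses how transcription and replication are arranged relative to each other and what CFAP20 contributes. Occupancy around TSSs came from 1 library per genotype, so differences between genotypes have no replicate check. Occupancy around replication origins came from 3 WT libraries. The CFAP20-KO library held 12.5% and the CFAP20/CCNC-dKO library 17.5% of the equivalent fragments of the WT library over TSS windows. No TSS of CFAP20 or CCNC was among those analysed here, so neither knockout could be checked at its target.

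The question of the first comparison was whether loss of CFAP20 changes RNAPII at promoters and in genes. At the 4894 TSSs above the median promoter density, median promoter density was 1.07 in WT and 1.10 in CFAP20-KO, and the median log2 ratio was 0.13 (bootstrap 95% interval 0.11 to 0.15), with 59.4% of these TSSs higher in CFAP20-KO. Over all TSSs the median log2 ratio was -0.030, so the direction depended on the density filter, and scaling to upstream density gave 0.19, or 0.20 with a window chosen after the data were examined. Gene body density was higher by a median log2 ratio of 0.08 (0.06 to 0.10, 4397 TSSs), and the promoter to gene body ratio by 0.05 (0.03 to 0.08). Across the alternative windows, filters and scalings the gene body ratio ranged from 0.0094 to 0.15 and the promoter to gene body ratio from -0.051 to 0.06. In the 3 WT libraries, the median log2 promoter to gene body ratio at TSSs inside origin windows had an SD of 0.28. For promoter density the nearest measure, density relative to the flank at 1211 TSSs, had an SD of 0.38.

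The most strongly reduced promoters in CFAP20-KO included CUL4B, which encodes a cullin scaffold of ubiquitin ligases (chromosome X, TSS at 120575794, hg38), with a density of 1.19 in WT, 0.00258 in CFAP20-KO, less than 0.5 equivalent fragments, and 0.299 in CFAP20/CCNC-dKO. The upper 95% counting limit of the CUL4B density in CFAP20-KO was 0.247 times that of WT. TMEM173, which encodes the innate immune adaptor STING (chromosome 5, 139482790), had a density of 1.46 in WT, 0.0490 from 1 fragment in CFAP20-KO, and 1.08 in CFAP20/CCNC-dKO. Its CFAP20-KO density was 0.0335 times that of WT (95% counting interval 0.000136 to 0.263). C5orf66-AS2, C3orf35 and KCNAB1-AS1 had no coverage in CFAP20-KO and CPZ less than 0.5 equivalent fragments (0.0284). In the order C5orf66-AS2, C3orf35, CPZ and KCNAB1-AS1 the upper 95% counting limits were 0.524, 0.567, 0.423 and 0.934 times WT. KCNAB1-AS1 had a WT density of 0.320 beside a WT flank of 0.317, so its lower value is relative to background. The densities of AC108868.5 and TDRD7, a tudor domain gene, rested on 1 fragment each and were 0.0584 and 0.0774 times those of WT (95% counting intervals 0.000305 to 0.444 and 0.00199 to 0.438). The flanks of these genes kept their density: at CUL4B the flank stood at 1.65 times the library median in WT and at 1.55 times in CFAP20-KO, and at TMEM173 at 0.935 and 0.921 times.

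The 8 promoters with the highest ratio in CFAP20-KO had WT densities of 0.121 to 0.262. These lay below their own WT flanks and below the WT median of 0.305 at TSSs without a BrU-seq value. They also lay below the filter limit of 0.411, which these promoters passed only through the knockout libraries. Their folds are thus relative to background. RP11-267C16.1, a noncoding RNA gene, had 0.168 in WT and 1.22 in CFAP20-KO (7.29-fold, 95% counting interval 3.48 to 15.1). LINC01389 was 7.44-fold (3.09 to 17.7), UCN3, which encodes urocortin 3, 7.15-fold (3.20 to 15.8) and LGALS14, a galectin gene, 5.35-fold higher (2.7 to 10.3). TMEM178A, RGPD8, ZNF429 and KIF12 were between 4.89-fold and 5.17-fold higher. RGPD8 has near-identical copies, so its value is uncertain, and UCN3 and LGALS14 lay in chromosome segments where flank density was also higher in the knockouts. Relative to the median ratio, 773 of 4892 genes were at least 1.5-fold higher and 813 at least 1.5-fold lower in CFAP20-KO. Without centring the counts were 1090 higher and 605 lower. Counting error alone would give 801 genes past 1.5-fold, against 1586 observed. With a wider promoter window 458 were higher and 545 lower, 20.5% of genes in total against 32.4% with the main window. At the 1211 TSSs that could also be read in the WT replicates, 29.9% passed 1.5-fold between CFAP20-KO and WT. Between WT replicate 1, the library used here, and replicates 2 and 3 these were 24.2% and 24.0%, and between replicates 2 and 3 33.7%. The WT shares came from wider bins with a relatively larger pseudocount and may be too low for this comparison.

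The question of the next comparison was what the combined loss of CFAP20 and CCNC does. Median promoter density was 0.828 in CFAP20/CCNC-dKO against 1.07 in WT, a median log2 ratio of -0.24 (-0.27 to -0.22), and 65.7% of the TSSs were lower. Gene body density differed little, with a median log2 ratio of 0.04 (0.02 to 0.05), and from -0.0055 to 0.06 across the alternatives, so the promoter to gene body ratio was also lower, by a median log2 ratio of -0.28 (-0.30 to -0.26). The lower promoter density kept its direction under each of the 8 alternatives run, between -0.25 and -0.19. Promoter over flank density was 2.39 in CFAP20/CCNC-dKO and 3.02 in CFAP20-KO at 1211 TSSs, and the 3 WT libraries gave 3.04, 2.37 and 3.5 (mean 2.97 ± 0.567, SD, n = 3). The CFAP20/CCNC-dKO value thus lay inside the range of WT. Within a library, the median log2 promoter to gene body ratio was 0.957 in CFAP20/CCNC-dKO and 1.32 in CFAP20-KO. In WT replicates 1, 2 and 3 it was 1.41, 1.05 and 1.55. The CFAP20/CCNC-dKO value thus lay below all 3 WT values. The gap to the lowest, replicate 2, was less than their SD of 0.257, and the gaps to replicates 1 and 3 were larger than that SD.

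**Figure D1:**
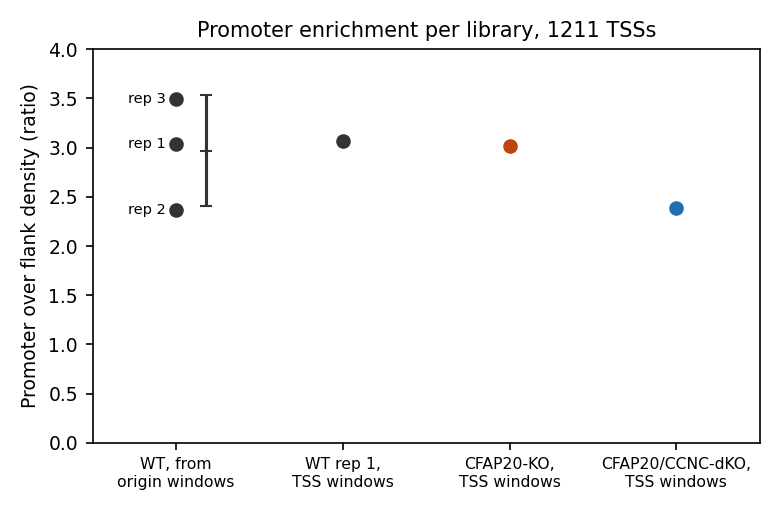
Ratio of mean promoter density to mean flank density at 1211 TSSs. Each point is 1 library; the 3 WT replicates were read from origin windows (bar, mean ± SD, n = 3) and 1 library per genotype from TSS windows, and the CFAP20/CCNC-dKO value of 2.39 lies next to the lowest WT value of 2.37.

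The promoters with the lowest ratio in CFAP20/CCNC-dKO against WT were ZNF543, RIMKLA, PNPLA8, CDC25B, AKR1B10, IL17RD, ZNF14 and RP11-138A9.2. CDC25B, which encodes a phosphatase that activates cyclin-dependent kinases (chromosome 20, 3795835), had 1.5 in WT, 0.810 in CFAP20-KO and 0.140 in CFAP20/CCNC-dKO, and the last was 0.0931 times WT (95% counting interval 0.0175 to 0.287). PNPLA8, a phospholipase gene on chromosome 7, was at 0.0927 times WT (0.0223 to 0.255) and IL17RD, an interleukin 17 receptor family gene on chromosome 3, at 0.100 times (0.0155 to 0.336). ZNF543, a zinc finger gene on chromosome 19, was at 0.0667 times (0.00845 to 0.240). RIMKLA had less than 0.5 equivalent fragments in CFAP20/CCNC-dKO (0.0110), with an upper 95% counting limit of 0.476 times WT. Of these 8 genes, 5 (ZNF543, PNPLA8, CDC25B, AKR1B10 and RP11-138A9.2) lay in segments where flank density was lower in both knockouts. The highest ratios were at RP11-267C16.1 (5.69-fold, 2.83 to 11.5), SATL1 (4.44-fold, 1.93 to 10.0), GSDMA, a gasdermin gene (4.18-fold, 2.01 to 8.52), HLA-DOA, an MHC class II gene (4.17-fold, 1.83 to 9.25), and MOGAT2, FAM187B, GTSCR1 and LGALS16 (3.62-fold to 4.04-fold). FAM187B and LGALS16 lay in a segment of higher flank density. The 8 genes with the highest ratios had WT densities of 0.142 to 0.285, below their own WT flanks. These were also below the WT median of 0.305 at TSSs without a BrU-seq value, so the folds are relative to background. Relative to the median, 921 genes were at least 1.5-fold higher and 818 at least 1.5-fold lower. Without centring these were 556 and 1372. Counting error alone would give 653 genes past 1.5-fold, against 1739 observed. At the 1211 TSSs, 32.0% passed 1.5-fold, more than between WT replicate 1 and the other WT libraries (24.2% and 24.0%) and less than between replicates 2 and 3 (33.7%). The WT shares, from wider bins and a relatively larger pseudocount, may be too low here as well.

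Cells lacking CCNC in addition to CFAP20 were also compared with cells lacking CFAP20 alone, which shared the antibody label. Promoter density was lower in CFAP20/CCNC-dKO by a median log2 ratio of -0.40 (-0.42 to -0.38), with 71.2% of TSSs lower; over all TSSs the ratio was -0.20. Gene body density had a median log2 ratio of -0.05 (-0.07 to -0.03), from -0.15 to -0.0076 across the alternatives, and the promoter to gene body ratio one of -0.33 (-0.37 to -0.30), or -0.18 over all TSSs. Promoters with less than 0.5 equivalent fragments in CFAP20-KO led the higher genes. Lower 95% counting limits were 3.49-fold for KCNAB1-AS1, 3.06-fold for C3orf35 and 2.58-fold for C5orf66-AS2. For the gene with identifier ENSG00000261058.1 (chromosome 16, 75119558), TLR1 (a Toll-like receptor gene) and CPZ they were 2.18-fold, 1.59-fold and 1.45-fold. TMEM173 was 22.1-fold higher (95% counting interval 2.59 to 5612) and RP11-196H14.2 17.3-fold higher (2.24 to 2210), each from 1 fragment in CFAP20-KO. Lower in CFAP20/CCNC-dKO was RIMKLA, with an upper 95% counting limit of 0.280 times CFAP20-KO. Also lower were AKR1B10, an aldo-keto reductase gene (0.0381 times, 5.22e-05 to 0.428), IL17RD (0.0975 times, 0.0139 to 0.379), AADAC (0.0972 times, 0.0126 to 0.396) and CASP1, which encodes the inflammatory caspase (0.102 times, 0.0139 to 0.405). RP11-807H7.2 was at 0.0846 times (0.00581 to 0.440). WT promoter density was near or below the WT flank at KCNAB1-AS1 (0.320 and 0.317) and AADAC (0.337 and 0.359). The same held for ENSG00000261058.1 (0.464 and 0.549) and RP11-196H14.2 (0.445 and 0.462). KCNAB1-AS1 and AADAC passed the filter limit of 0.411 only through 1 knockout library each. The ratios of these genes are thus uncertain. C17orf98 is left out because its listed position had no match in GENCODE 44 and may not be that of the gene. By the 1.5-fold rule 1018 genes were higher and 866 lower (521 and 1881 without centring), and counting error alone would give 1237. At the 1211 TSSs read in the WT replicates, 34.3% passed 1.5-fold, against 24.2%, 24.0% and 33.7% between WT libraries, whose shares may be too low.

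Flank density along the chromosomes differed between the knockouts and WT in 6 segments. On chromosome 7 from 105876604 to 158856578 the median flank density was 1.00 times the library median in WT, 0.535 times in CFAP20-KO and 0.551 times in CFAP20/CCNC-dKO (185 TSSs). On chromosome 20 from 142369 to 25863201 the values were 1.01, 0.553 and 0.497 (112 TSSs), with like decreases on chromosome 7 from 64140495 to 76627241 (43 TSSs) and chromosome 19 from 54906150 to 58599277 (59 TSSs). On chromosome 10 from 5234358 to 30433937 the WT library had 0.689 against 0.969 and 1.02 in the knockouts (81 TSSs), and all 3 WT replicates were low there at origins (0.650, 0.667 and 0.667 times their medians). On chromosome 19 from 35228729 to 39846414 the values were 0.972 in WT, 1.54 in CFAP20-KO and 1.64 in CFAP20/CCNC-dKO (45 TSSs), while the 1 origin there had 1.90, 1.83 and 2.33 in the WT replicates. In the 4 lower segments, 115 of 163 genes (70.6%) were at least 1.5-fold lower in CFAP20-KO and 131 (80.4%) in CFAP20/CCNC-dKO, against 15.0% and 14.7% of 4657 genes elsewhere.

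**Figure D2:**
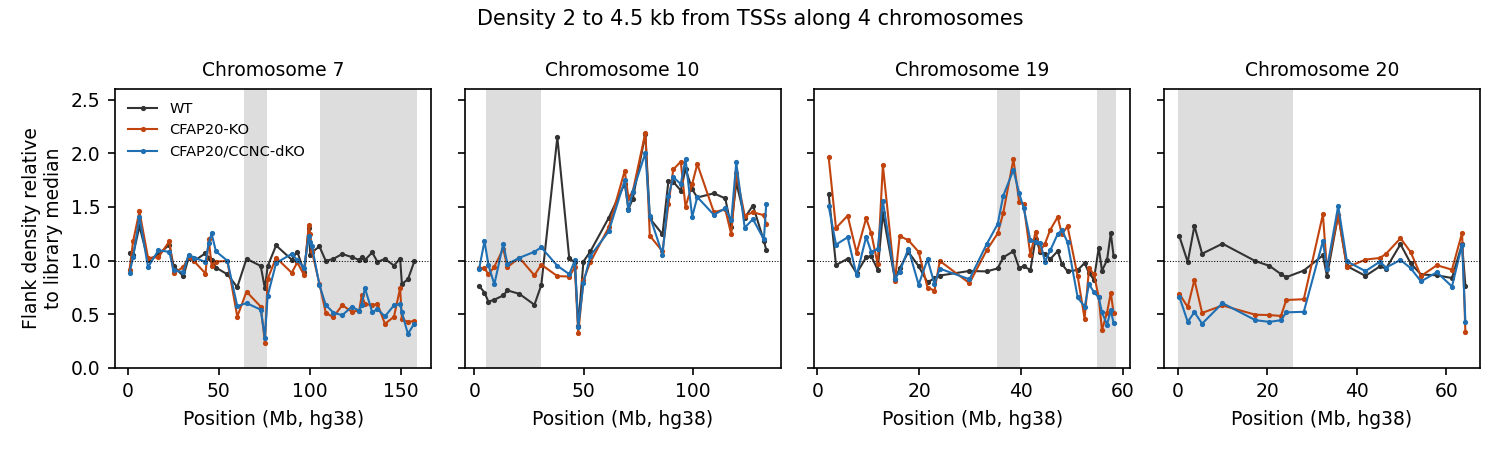
Density 2 to 4.5 kb from TSSs relative to the library median (vertical axis) against position in Mb (horizontal axis) on chromosomes 7, 10, 19 and 20, as medians of blocks of neighbouring TSSs; grey marks the 6 segments. In the segment at the end of chromosome 7 both knockouts lie at 0.535 and 0.551 and WT at 1.00.

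Gene lists fixed before the data were examined were described next. Of 162 percentiles (18 lists, 3 comparisons, and promoter, gene body and promoter to body ratio), 12 lay outside the central 95% of random lists, where 8.1 would be expected by chance. Core Mediator subunits had a lower promoter ratio in CFAP20-KO against WT (median log2 ratio -0.46, percentile 2.42): 4 of 7 measured members were at least 1.5-fold lower and none higher. Over all genes, 813 of 4892 were at least 1.5-fold lower. MED7 had 1.72 in WT and 0.846 in CFAP20-KO (0.491 times, 95% counting interval 0.241 to 0.898), MED17 had 2.15 and 2.08, MED18 1.36 and 1.51, and MED21 1.64 and 1.05. With another choice of TSS per gene the percentile was 2.68, inside the central 95%, so this call depended on that choice. Interferon response genes were at percentile 1.93 (median -0.34), with 2 of 8 members at least 1.5-fold lower. IFIT3 had 2.44 in WT, 1.83 in CFAP20-KO and 1.44 in CFAP20/CCNC-dKO. IRF9 had 2.41, 1.92 and 1.37, and IFIT2 1.51, 1.58 and 1.22.

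Extracellular matrix and adhesion genes had a higher gene body ratio in CFAP20-KO against WT (median log2 ratio 0.62, percentile 99.7, 2 of 7 members at least 1.5-fold higher) and a lower one in CFAP20/CCNC-dKO against CFAP20-KO (-0.76, percentile 0.100, 4 members lower), with a promoter to body ratio of 0.74 (percentile 99.8). Gene body density of TGFBI was 0.685 in WT, 1.09 in CFAP20-KO and 0.532 in CFAP20/CCNC-dKO, and that of ITGA5, an integrin gene, was 1.08, 1.69 and 1.40. LOX, the lysyl oxidase gene, did not follow in CFAP20-KO, with 0.805, 0.726 and 0.655. Immediate early genes had a lower gene body ratio in CFAP20/CCNC-dKO against WT (-0.39, percentile 0.130, 4 of 12 lower): CYR61 had 10.7 in WT and 7.46, MYC 1.97 and 0.951, and KLF2 1.57 and 0.880, while DUSP5 had 1.67 and 2.16. Their promoters had 3 of 12 lower and 1 higher. Of the immediate early genes, FOS and EGR1 are 3457 and 3826 bp long, so their gene body window runs past the gene end. Replication origin and fork proteins had a higher gene body ratio in CFAP20/CCNC-dKO against WT (0.33, percentile 99.7, 2 of 16 higher), whereas none of their promoters was higher and 1 was lower; gene body density of the origin licensing genes ORC5, ORC6, CDC6 and MCM2 was 0.386, 0.338, 0.509 and 0.409 in WT and 0.484, 0.551, 0.688 and 0.389 in CFAP20/CCNC-dKO. MCM10, which is 1 of the 2 members counted higher (0.313 and 0.547), lay in a segment of higher flank density, and GINS1 (0.450 and 0.320) in a lower one. Pausing and elongation factors were at percentile 98.0 for the promoter to body ratio in CFAP20/CCNC-dKO against WT (0.14). Heat shock and unfolded protein response genes were at percentile 98.4 for gene bodies in CFAP20/CCNC-dKO against CFAP20-KO (0.34). Gene body density of HSP90AA1, DNAJB1, CHAC1 and HSPH1 was 1.24, 1.63, 0.415 and 0.400 in CFAP20-KO and 0.766, 1.53, 0.951 and 0.520 in CFAP20/CCNC-dKO. HSP90AA1, a chaperone gene, had promoter densities of 6.65 in WT, 6.52 in CFAP20-KO and 3.74 in CFAP20/CCNC-dKO (0.563 times WT, 95% counting interval 0.437 to 0.715), DNAJB1 had 4.99, 4.64 and 3.38, and HSPH1 1.92, 0.789 and 2.78. The neuron marker list (4 genes) gave 3 of the 12 outlying percentiles, all in CFAP20/CCNC-dKO against WT (98.3 for promoters, 1.92 for gene bodies, 99.8 for their ratio). Neuron markers were 1 of the lists of genes this line should not express. Their median promoter densities of 0.336 in WT and 0.377 in CFAP20/CCNC-dKO were near background, so outlying percentiles also arose at background. NEUROD1 had promoter densities of 0.354 in WT and 0.898 in CFAP20/CCNC-dKO, STMN2 0.318 and 0.417, and SNAP25, in the chromosome 20 segment, 1.05 and 0.121.

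The other lists stayed inside the central 95% in every comparison. At promoters in CFAP20-KO against WT, 2 of 14 cytosolic ribosomal protein genes were at least 1.5-fold higher and none lower; RPL26 had 2.53 in WT and 4.31 (1.70-fold, 95% counting interval 1.25 to 2.27), RPS24 4.25 and 5.73, RPS14 3.19 and 3.67, and RPL19 2.91 and 2.7. Of 8 p53 target genes, 2 were higher and none lower in CFAP20-KO, and 1 was higher and 2 lower in CFAP20/CCNC-dKO. Over all 4892 genes, 773 were higher and 813 lower in CFAP20-KO, and 921 and 818 in CFAP20/CCNC-dKO. The line carried a p53 knockout per the labels, so the counts of p53 target genes do not measure a p53 response. PLK2, a polo-like kinase gene, had 5.04 in CFAP20/CCNC-dKO against 9.44 in WT (0.534 times, 0.430 to 0.655). Mitotic genes had 2 of 11 lower in CFAP20-KO, and 1 higher and 1 lower in CFAP20/CCNC-dKO; CENPA, the centromeric histone gene, had 1.27 in WT and 2.21 in CFAP20/CCNC-dKO (1.73-fold, 1.20 to 2.44). Among R-loop and transcription-coupled repair factors 1 of 9 was lower in CFAP20-KO and none passed 1.5-fold in CFAP20/CCNC-dKO relative to the median, where RNASEH2B, which encodes a subunit of ribonuclease H2, had 1.30 against 2.34 in WT. Cilium and flagellum genes had 2 of 11 lower in CFAP20-KO, and 1 higher and 1 lower in CFAP20/CCNC-dKO; BBS2, a Bardet-Biedl syndrome gene, had 1.84 in WT, 1.5 in CFAP20-KO and 0.615 in CFAP20/CCNC-dKO (0.334 times WT, 0.171 to 0.594). Of 4 cholesterol synthesis genes, 1 was lower in CFAP20-KO. None of the 5 housekeeping genes passed 1.5-fold in either knockout against WT; EEF1A1 had 9.67, 9.48 and 6.91 in WT, CFAP20-KO and CFAP20/CCNC-dKO. Retinal pigment epithelium markers had 1 of 7 higher and 1 lower in CFAP20-KO and none past 1.5-fold in CFAP20/CCNC-dKO; OTX2 had 1.68, 1.81 and 1.01, and MITF 0.540, 0.751 and 0.523. Blood cell and hepatocyte markers, genes this line should not express, gave background densities: CD8A had 0.422, 0.601 and 0.380, and ALB 0.354, 0.508 and 0.424. With 2 measured members each, RNAPII subunits and replication-dependent histones were not placed: POLR2K had 1.39, 1.66 and 1.24, and HIST1H4H 4.24, 4.52 and 5.36. The knockout targets, the Mediator kinase module and long genes at common fragile sites had no measured member.

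RNAPII density was set beside the WT BrU-seq gene body value, available for 6306 TSSs. Across TSSs, which are not independent replicates, Spearman's correlation with promoter density was 0.70 in WT, 0.63 in CFAP20-KO and 0.63 in CFAP20/CCNC-dKO. With gene body density it was 0.62, 0.51 and 0.48 (5728 TSSs). The knockout libraries held 12.5% and 17.5% of the WT equivalent fragments. Lower depth by itself lowers a rank correlation, so the lower values do not show a looser relation in the knockouts. The median log2 promoter ratio of CFAP20/CCNC-dKO to WT was -0.07, -0.19, -0.34 and -0.40 in quartiles 1 to 4, while in CFAP20-KO it was -0.04, 0.0077, 0.03 and 0.04. Promoters of quartile 1 had a WT median of 0.341, near that of TSSs without a BrU-seq value, which by itself brings their ratios near 0. In quartile 4 the mean profile peaked 80 bp downstream of the TSS at 2.86 in WT, at 90 bp and 2.40 in CFAP20-KO, and at 100 bp and 1.66 in CFAP20/CCNC-dKO. After widening the WT coverage to the fragment length of the knockout libraries, the WT maximum was 2.66. Gene body medians in that quartile, which include genes shorter than 5000 bp, were 0.526 in WT, 0.610 in CFAP20-KO and 0.540 in CFAP20/CCNC-dKO. TSSs without a BrU-seq value had promoter medians of 0.305, 0.266 and 0.277, close to the flank density, which shows the background of the measurement.

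**Figure D3:**
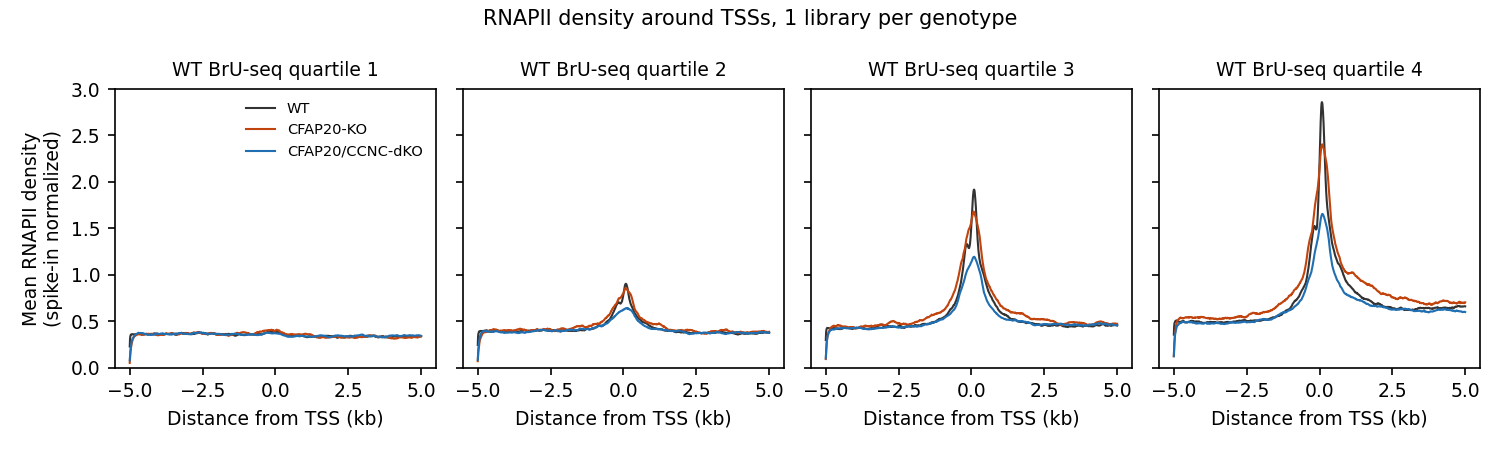
Mean spike-in normalized RNAPII density (vertical axis) against distance from the TSS in kb (horizontal axis) for quartiles 1 to 4 of WT BrU-seq signal, 1 library per genotype. In quartile 4 the maxima are 2.86 in WT, 2.40 in CFAP20-KO and 1.66 in CFAP20/CCNC-dKO, and in quartile 1 the 3 lines run together.

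TSSs within 10 kb of a selected origin were compared with other TSSs of like promoter density, to ask whether genotype ratios differ next to origins. For these 376 TSSs the median log2 promoter ratio was 0.04 in CFAP20-KO against WT (percentile 31.5), -0.31 in CFAP20/CCNC-dKO against WT (percentile 27.0) and -0.42 in CFAP20/CCNC-dKO against CFAP20-KO (percentile 14.5). Gene body percentiles were 6.21, 55.5 and 28.4. None lay outside the central 95%. Within 25 kb (780 TSSs) the promoter percentiles against WT were 2.68 in CFAP20-KO and 2.38 in CFAP20/CCNC-dKO, the latter just outside.

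Around 2040 origins in WT, RNAPII density was set against flanking DNA to ask how transcription lies relative to replication start sites. Density at origin centres was close to that 75 to 100 kb away: the ratio was 0.987, 1.01 and 1.00 in replicates 1, 2 and 3, a mean log2 ratio of 0.0018 ± 0.019 (SD, n = 3, exact sign-flip permutation test, two-sided, p = 1). Against a flank of 25 to 50 kb it was -0.067, lower in 3 of 3 libraries. The positive side, in the direction of transcription of the nearest gene, was higher than the negative side in 3 of 3 libraries, 1.09-fold, 1.05-fold and 1.13-fold (mean log2 ratio 0.13 ± 0.05, SD, n = 3, exact sign-flip permutation test, two-sided, p = 0.25, the smallest this design allows). The smoothed mean profile was highest at 13 to 25 kb on the positive side, at 1.14, 1.10 and 1.21 times. The sides are set by the nearest gene, and per the file name the origins were selected for an empty 5 kb upstream of a TSS, so the difference between the sides is not independent of how origins were chosen and oriented. Of the origins, 1483 (72.7%) lay upstream of the nearest TSS, at a median distance of 13.1 kb over all origins. Across origins, which are not replicates, the density within 100 kb had Spearman correlations of 0.95, 0.96 and 0.93 between pairs of WT libraries.

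**Figure D4:**
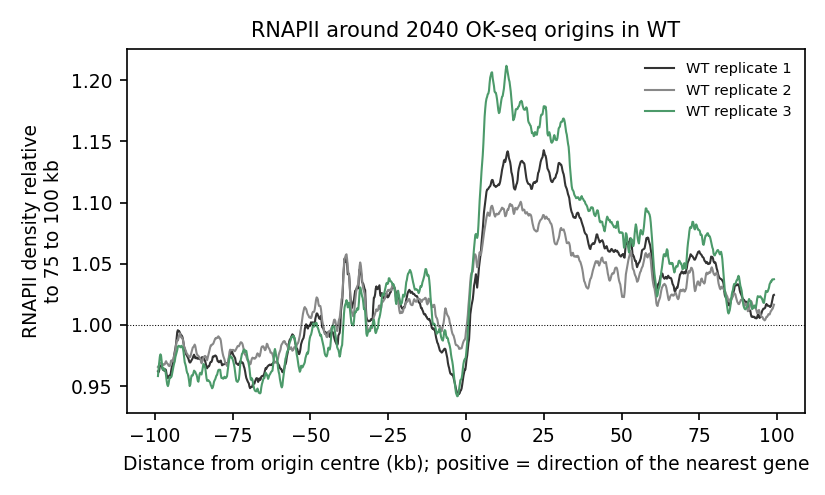
RNAPII density relative to the mean 75 to 100 kb away (vertical axis) against distance from the origin centre in kb (horizontal axis, positive in the direction of transcription of the nearest gene), 1 line per WT replicate over 2040 origins. All 3 lines have their maximum on the positive side (1.14, 1.10 and 1.21), the side towards which the nearest gene is transcribed.

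The 5 origins with the highest density within 5 kb are given with mean ± SD (n = 3). The origin at chromosome 1, 143267001 (nearest gene LSP1P5, a pseudogene 155591 bp away), had 7.53 ± 3.06. That at chromosome 6, 73514501 (nearest SNORD141B, 3937 bp away), had 6.95 ± 2.67. On chromosome 2, 89832001 (nearest LOC101927050, 194094 bp away) had 5.33 ± 3.56, and 47177501 (nearest CALM2, a calmodulin gene, 565 bp away) 3.33 ± 0.701. The origin at chromosome 10, 35610001 (nearest GJD4, 4660 bp away), had 3.04 ± 0.698. These are means over libraries whose scales may differ. At the origin near GJD4 the flank was as dense, 3.21, so no local peak was measured there.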

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

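The deposited origin densities also covered 2744 origins outside the table of selected origins, which no comparison above used. They are listed here because they hold a signal that was not analysed. At their centres RNAPII density was 1.03, 1.04 and 1.07 times that 75 to 100 kb away in WT replicates 1, 2 and 3, a mean log2 ratio of 0.065 ± 0.030 (SD, n = 3, exact sign-flip permutation test, two-sided, p = 0.25, the smallest possible). The difference from the selected origins was not tested.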

How the results depend on the processing

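The settings without the 6 segments, with widened WT coverage, with GENCODE positions, with scaling to -4000 to -3000 bp and with the flank ratio subtracted were chosen after seeing the data. Median ratios between genotypes were compared with the SD of flank-relative density between WT libraries, a rough limit, and counts with a factor of 1.5. Ratios at origins were compared by direction only, and BrU-seq correlations by a bootstrap interval. Of 121 alternative values of the main results, 98 stayed within these limits in the same direction. The limits of 0.38 for promoter density and 0.28 for promoter to body are larger than or near most of these ratios. A value of the same sign thus mostly stayed within them, and the number 98 says little about robustness. The lower promoter density and promoter to body ratio in CFAP20/CCNC-dKO kept their direction in every setting run. Over all TSSs, the CFAP20-KO against WT ratio turned to -0.030 for promoters and -0.051 for promoter to body. With the gene body window from 1000 to 3000 bp, the CFAP20-KO against WT promoter to body ratio turned to -0.0061, the CFAP20/CCNC-dKO against WT gene body ratio to -0.0055, and the CFAP20/CCNC-dKO against CFAP20-KO gene body ratio moved to -0.15. The causes were not tested. Over all TSSs (9767 genes) the counts were 1900 higher and 2399 lower in CFAP20-KO against WT, 1919 and 2003 in CFAP20/CCNC-dKO against WT, and 2716 and 2378 in CFAP20/CCNC-dKO against CFAP20-KO. Without centring the last 2 comparisons gave 556 and 1372, and 521 and 1881. The promoter window from -500 to 1000 bp gave 458 higher and 545 lower in CFAP20-KO against WT. Without the 6 segments the counts were 711 and 709 (CFAP20-KO against WT), 859 and 715 (CFAP20/CCNC-dKO against WT), and 969 and 813. Within 25 kb of origins 1 of 6 percentiles was outside the central 95%, against 0 within 10 kb.

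The log2 ratio at origin centres, near 0, turned to -0.054 with the median over origins, -0.019 at origins with no listed TSS within 10 kb and -0.067 against a flank of 25 to 50 kb; without 1 replicate it ranged from -0.0067 (without replicate 2) to 0.012 (without replicate 1), with -0.00025 without replicate 3. The ratio of the 2 sides stayed positive, from 0.10 to 0.15 without 1 replicate. Agreement of WT libraries at origins, the median of 3 pairs, moved from 0.95 to 0.69 with a window of 5 kb. Of 1560 alternative values of the single genes kept here, 1545 stayed within counting error and 15 moved past it. The alternatives reused mostly the same fragments, and counting error is wide at this depth, so the number 1545 says little about robustness. No genotype library could be left out, with 1 per genotype. No paired analysis was possible because the groups share only replicate number 1 and no test compared them. Depth limits single genes, with a median of 14.4 equivalent fragments per promoter in CFAP20-KO.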

Other observations

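The classes of origins, the reading of single flanks and the tests of ChIP enrichment, of the spread between WT libraries and of flank density were chosen after the results were seen. The asymmetry of RNAPII around origins was computed by the position of the nearest gene. At 1099 origins upstream of a TSS within 20 kb the positive side was 1.19, 1.12 and 1.26 times the negative side in WT replicates 1, 2 and 3. At 259 origins downstream of a TSS within 20 kb the values were 0.964, 0.994 and 0.967, at 355 origins 20 to 50 kb from a TSS 1.04, 1.03 and 1.06, and at 327 origins over 50 kb from a TSS they were 0.895, 0.909 and 0.899. Centres were 0.964, 0.994 and 0.979 times as dense as the flank in the first class, 1.06, 1.07 and 1.12 times downstream within 20 kb, 0.926, 0.969 and 0.936 times at 20 to 50 kb, and 1.08, 1.09 and 1.08 times over 50 kb. The difference between these classes was not tested.

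CUL4B was among the promoters low in both knockouts (0.00258 in CFAP20-KO, 0.299 in CFAP20/CCNC-dKO, 1.19 in WT), while the density of its flanks was 1.65, 1.55 and 1.16 times the library median in WT, CFAP20-KO and CFAP20/CCNC-dKO. AC108868.5 (0.884, 0.0516 and 0.393) and ZNF14 (0.951, 0.428 and 0.0880) were also low in both and lay outside the 6 segments. TMEM173 was low in CFAP20-KO only, with 0.0490 against 1.46 in WT and 1.08 in CFAP20/CCNC-dKO. These genes were named by rule for their extreme ratios.

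The first pattern was the lower promoter density in CFAP20/CCNC-dKO than in WT. Widening the WT coverage left the median log2 ratio at -0.24, which argues against fragment length. A difference in ChIP enrichment between libraries remains open, since the CFAP20/CCNC-dKO enrichment of 2.39 lay inside the WT range of 2.37 to 3.5. However, its median log2 promoter to gene body ratio of 0.957 lay below the WT values of 1.41, 1.05 and 1.55. The gap to the lowest WT value was less than their SD of 0.257, and the gaps to the other WT values were larger than that SD. GC content may contribute: the median log2 ratio was -0.045 in the lowest GC quintile and -0.27 to -0.31 in the other 4, but WT promoter density there was lower (0.543 against 1.15 to 1.30), which by itself brings ratios nearer 0. The loss of CCNC, named by the design, and the antibody of the labels stay open too, the antibody only against WT, as the ratio to CFAP20-KO was -0.40.

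The second pattern was the count of promoters past 1.5-fold in CFAP20-KO. Counting error alone gave 801 in simulation, with a maximum of 858 in 100 draws, against 1586 observed, so it is not the whole source. The bound set beforehand for ruling it out, below 50% of the observed count, was narrowly missed, so counting error could account for a large part. The spread between libraries of 1 genotype stays open as a source: 33.7% of promoters passed 1.5-fold between WT replicates 2 and 3, against 29.9% between CFAP20-KO and WT. Between WT replicate 1, the library used, and the others 24.2% and 24.0% passed. The WT shares came from wider bins and a relatively larger pseudocount and may be too low. An effect of CFAP20 loss on some of these genes is not excluded.

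The third pattern was the lower density on parts of chromosomes 7, 19 and 20 in both knockouts. TSSs elsewhere matched on GC had a median flank log2 ratio of 0.027, which argues against GC content. Fewer DNA copies of these segments in the knockout cells stay open as a candidate explanation, with no independent test run: the segments were chosen for flank log2 ratios lower by more than 0.35 in both knockouts. The median flank log2 ratios of -0.76 in CFAP20-KO and -0.82 in CFAP20/CCNC-dKO restate that choice. No biological explanation was tested.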
